A study of Mus musculus and Homo sapiens with 10 samples.

How the data were processed

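Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate proteins and histone marks on the genomes of 3 cell lines. NIH3T3 is an immortalized mouse fibroblast line. HMEC is a line of human mammary epithelial cells immortalized with telomerase (TERT), and HMLER is its tumorigenic derivative, which carries the SV40 large T antigen, TERT and an oncogenic HRAS allele. Per the labels' protocols, exponentially growing cells were harvested for ChIP and libraries were made with an Illumina ChIP-seq kit. The 10 lists analysed were UBF, Pol I, Pol II, H3K4me3, H3K9ac, H4 hyperacetylation and H3K9me3 in NIH3T3 (7 lists), and UBF in HMEC, Pol I in HMEC and UBF in HMLER (3 lists). The Pol I antibodies were raised against its largest subunit, POLR1A, and the Pol II antibody was described as recognising the phosphorylated C-terminal repeat. The genomic DNA inputs named in the series' design were not analysed here.

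The authors deposited 1 list of called peaks per antibody and cell line, in 3 columns that hold the chromosome, the start and the end of each peak. The lists carry no score, height, fold enrichment, p-value or read count, so the sequencing depth behind each peak is unknown and peaks could not be ranked by strength. CASAVA 1.8.2, BWA and Picard, and the builds mm9 and hg19, are named in the submitters' processing notes. The peak caller, its threshold and the filters applied are not given in the sources used here. The design names 2 biological replicates for UBF in NIH3T3, yet 1 list stands for them, and whether the replicates were pooled is not given. Each list was therefore treated as 1 sample (n = 1), there is no replicate error, and no test between cell lines was possible. Intervals of shares are exact (Clopper-Pearson) 95% binomial intervals over peaks, and those of odds ratios are 95% normal intervals on the log scale. They cover counting error only, and peaks are not independent replicates.

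Lines were split at carriage returns, and the NIH3T3 Pol I list, which has no header line, was read from its first line. Coordinates are given as in the files, whose counting origin (0 or 1) is not given in the sources used here. The builds were taken from the submitters' processing notes. Every mouse list holds peaks on chromosome 1 that end beyond the last gene of the GRCm38 gene table provided with the data (5 in the UBF list), which does not by itself exclude that build. No mm9 or hg19 annotation was used here. Peaks are therefore identified by position, peaks near transcription start sites were not counted, and the gene lists fixed beforehand could not be tested. The lists name unplaced contigs in different ways, so peaks on contigs could not meet a peak of a list with other names. In the NIH3T3 UBF list 49 peaks lie on contigs or chromosome Y. Their effect is covered by an alternative without contigs.

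A peak was called shared if at least 1 bp of it was covered by a peak of the other list. Each share was set beside 1000 random placements (100 for the alternatives), in which every peak of the first list was moved to a random position on its own chromosome, keeping its width, within the range that the lists of that species cover. The ratio of the observed share to the mean of the placements is the share over random, and its interval is the interval of the share divided by that mean. The placements took no account of genes, open chromatin or repeats, so a ratio above 1 does not tell shared binding from shared background. For the comparison at active promoters, H3K4me3 peaks were divided by the presence of a UBF (or Pol I) peak, and the share with another mark was compared with Fisher's exact test (two-sided, across peaks, Benjamini-Hochberg over 8 tests). The 8 odds ratios were also stratified by H3K4me3 width, and that of H3K9me3 at H3K4me3 peaks with Pol II by width and by Pol II coverage, with the Mantel-Haenszel method. Width groups are 4 groups of nearly equal size, cut at the quartiles of width, except where 10 groups are named. Clusters were counted in fixed 100-kb windows by peak centre, and set beside the fullest window of each of 100 random placements. Peaks named individually were chosen by a rule fixed before the data were examined: the 10 strongest peaks of each UBF and Pol I list, the 10 strongest of HMEC and HMLER absent from the other line, and the 10 strongest shared. With no score in the files, strength fell to the last criterion of the rule, peak width. For each UBF and Pol I list the rule also asked for peaks near a transcription start site. That condition could not be applied without an annotation, so the peaks were taken from anywhere in the list. The 10 fullest windows of each of these lists were added after the data were seen.

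The overlap and placement code was tested on simulated data: in lists of 3000 simulated peaks with 10% and 50% planted overlaps, 10.4% and 50.9% were recovered, and 0.31% where none was planted. The alternatives were a stricter overlap (at least 50% of the peak covered), a looser one (peak centre within 1000 bp), a circular shift in place of independent placement, removal of contigs, chromosome M and chromosome Y, and removal of the widest 5% of UBF peaks. Added after the data were seen were the wider 50% of each list, human peaks set to 500 bp, a reduced HMLER list, a UBF list without H3K9me3 and the stratification of the 8 odds ratios by width. Settings chosen beforehand that rank peaks by the authors' score, or that use the distance to transcription start sites, could not be run. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.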

Results

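Binding of the upstream binding factor (UBF), a transcription factor of RNA polymerase I (Pol I) known for its place on the ribosomal RNA genes, was mapped across the mouse and human genomes. In NIH3T3 fibroblasts the UBF list held 3704 peaks with a median width of 981 bp, and the Pol I list held 1409 peaks with a median of 230 bp. The other NIH3T3 lists were larger: 30239 peaks for Pol II, 27982 for H3K4me3 and 28308 for H3K9ac, both marks of active promoters, 41519 for H4 hyperacetylation, a mark of open chromatin, and 23795 for H3K9me3, a mark of silent chromatin. In human cells the lists held 9478 UBF peaks and 9294 Pol I peaks in HMEC, and 32274 UBF peaks in HMLER. Each list stands for 1 sample, the depth is unknown, and the values below describe these lists without replicate error.

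The first question was whether UBF in NIH3T3 cells lies where Pol I, Pol II and active or silent chromatin lie. In the whole list, UBF fell into 2 groups of almost equal size, a balance that changed with peak width, as given below. Of its 3704 peaks, 1759 (47.5%, interval 45.9 to 49.1) overlapped Pol II and all 3 active marks together, and 1707 (46.1%, 44.5 to 47.7) overlapped none of Pol II, the active marks or H3K9me3. A further 201 peaks (5.43%) had some but not all of Pol II and the active marks. Silent chromatin alone held 37 UBF peaks (0.999% of the list, 0.704 to 1.37), which lay in H3K9me3 without Pol II or an active mark. They were among 1744 peaks without Pol II or an active mark. Random placement of the whole UBF list met H3K9me3 at a mean of 2.11%, so the low count does not show that UBF avoids silent chromatin.

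Taken list by list, UBF peaks overlapped Pol II at 50.5% (48.9 to 52.2), H3K4me3 at 49.3% (47.7 to 50.9), H3K9ac at 49.1% (47.5 to 50.7) and H4 hyperacetylation at 50.2% (48.5 to 51.8). Random placement gave means of 2.21%, 3.38%, 3.30% and 4.06%. Among Pol II and the active marks, the ratio to random was highest for Pol II, at 22.8 (22.1 to 23.6), against 14.6 for H3K4me3, 14.9 for H3K9ac and 12.3 for H4 hyperacetylation. The observed shares were nearly equal, so this order comes from the placement means. Those were lowest for Pol II, whose list covers 26.8 Mb, against 54.5 to 63.8 Mb for the active marks. The order does not show that UBF prefers Pol II to the active marks. H3K9me3 was met by 16.2% of UBF peaks (15.0 to 17.4), which was 7.67 times random placement. Of these 600 peaks, 513 also had Pol II and all 3 active marks. None of the 1000 placements reached the observed share for any of the 6 lists, Pol I included.

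**Figure D1:**
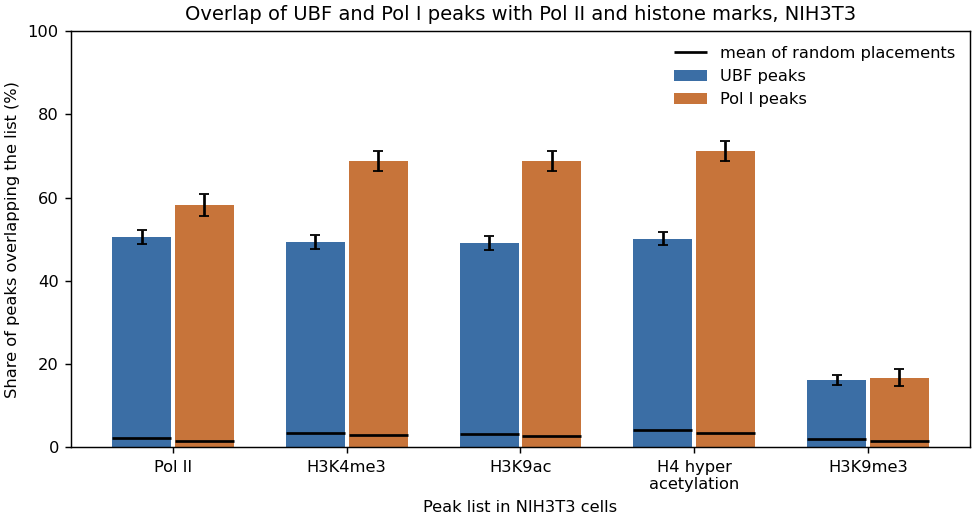
Share of UBF and Pol I peaks (%) that overlap each Pol II or histone list in NIH3T3 cells by at least 1 bp; bars are 1 list each, error bars are exact 95% binomial intervals over peaks and black lines are the means of 1000 random placements. Both lists stand far above random placement for Pol II and the active marks, and H3K9me3 has the lowest shares, at 16.2% and 16.7%.

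The 2 groups of UBF peaks differed in width. The peaks with Pol II and all active marks had a median width of 1153 bp and those in none of the 5 Pol II and histone lists a median of 865 bp. In the narrowest of 4 width groups of the UBF list (216 to 832 bp), 14.6% of peaks had Pol II and all active marks, and 81.1% met none of the 5 lists. In the widest group (1195 to 6865 bp) these shares were 87.9% and 6.60%. Chromosomes also differed. On chromosome 11, 66.1% of 236 UBF peaks (59.7 to 72.1) had Pol II and all active marks, against 9.86% of 71 peaks (4.06 to 19.3) on the X chromosome.

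**Figure D2:**
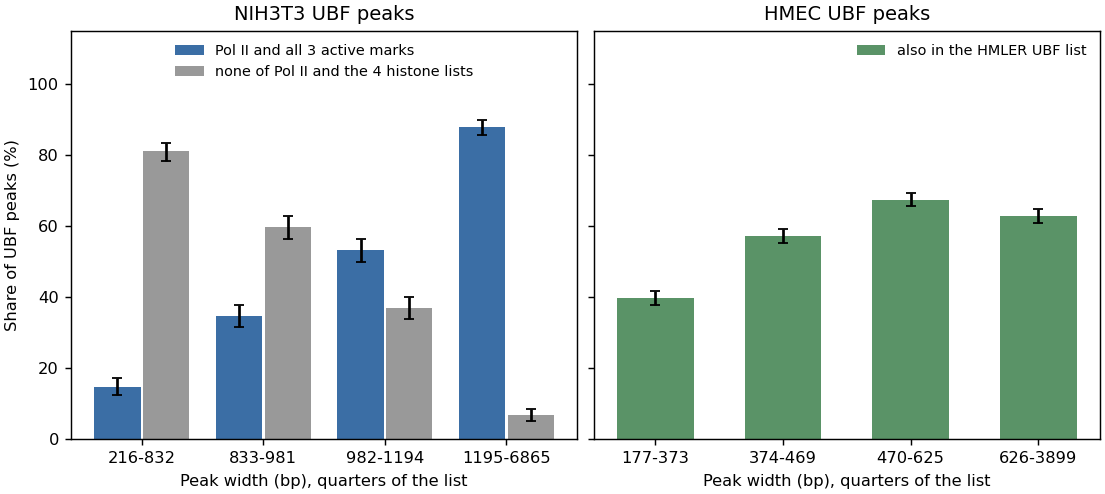
Left, share of NIH3T3 UBF peaks (%) with Pol II and all 3 active marks (blue) or in none of the Pol II and histone lists (grey), by width group in bp; right, share of HMEC UBF peaks (%) also present in HMLER, by width group; error bars are exact 95% binomial intervals. From the narrowest to the widest NIH3T3 group the active class goes from 14.6% to 87.9%, and in HMEC the shared part is 39.7% in the narrowest group, 67.5% in the next to widest and 62.9% in the widest.

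Among active promoters, taken as the H3K4me3 peaks, UBF and Pol II occurred together. Of the 1794 H3K4me3 peaks with UBF, 97.6% (96.8 to 98.3) had a Pol II peak, against 50.1% (49.5 to 50.7) of the 26188 without UBF. The odds ratio was 40.5 (29.9 to 54.9), with a Fisher's exact p too small for double precision. It was 23.9 (18.8 to 30.5) with a centre within 1000 bp, and 10.6 (8.15 to 13.9) in the wider 50% of each list. Stratified by 10 groups of H3K4me3 width it was 13.2 (9.23 to 18.8). The wider lists and the stratification here and below were added after the data were seen. The H3K4me3 peaks with UBF were wide, with a median of 3021 bp (quartiles 2370 and 3995) against 1610 bp without UBF, and Pol II was commoner in wide H3K4me3 peaks with or without UBF. Within width groups the difference in Pol II remained: in the next to widest of 4 H3K4me3 width groups (1686 to 2547 bp) Pol II was present at 97.4% (95.4 to 98.7) of peaks with UBF and 69.6% (68.5 to 70.7) of those without. In the widest group the shares were 99.5% (98.9 to 99.8) and 93.6% (92.9 to 94.2). UBF itself was present at 0.729% of H3K4me3 peaks in the narrowest group and at 17.7% in the widest.

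The same division gave higher shares of the other marks at H3K4me3 peaks with UBF. H3K9ac was present at 99.2% of those with UBF and 83.9% of those without (Fisher's exact adjusted p = 1.79e-106). H4 hyperacetylation was present at 99.3% and 86.3% (Fisher's exact adjusted p = 8.89e-89). Stratified by 10 width groups, the odds ratios fell from 22.8 to 4.37 (2.45 to 7.78) for H3K9ac and from 21.7 to 3.79 (2.12 to 6.78) for H4 hyperacetylation. In the widest of 4 groups, with 1236 of the peaks with UBF, H3K9ac stood at 100% and 99.8%, and H4 hyperacetylation at 99.9% and 99.8%. In the next to widest, with 428, they stood at 100% and 97.4%, and at 100% and 97.6%. The gaps were larger in the narrowest group, with 51, at 76.5% and 58.0%, and at 84.3% and 64.9%. H3K9me3, the silent mark, was also commoner, at 31.3% (29.2 to 33.5) with UBF and 12.7% (12.3 to 13.1) without (Fisher's exact adjusted p = 7.70e-86). Its odds ratio fell from 3.12 (2.81 to 3.47) to 1.76 (1.57 to 1.97) when stratified by 10 width groups. At the H3K4me3 peaks that also had Pol II it was 2.09, and 1.44 (1.28 to 1.62) when stratified by width and Pol II coverage. There the share of H3K9me3 was lower with UBF than without in groups 2 to 4 of 10 width groups, at 9.09% against 10.5%, 10.0% against 10.8% and 12.3% against 13.1%, with 44, 90 and 106 peaks with UBF. Dividing the H3K4me3 peaks by Pol I in place of UBF gave 84.9% with Pol II where Pol I was present and 52.1% where it was not, an odds ratio of 5.17 (4.30 to 6.20). The H3K4me3 peaks with Pol I were also wide, with a median of 2754 bp against 1653 bp without, and the odds ratio stratified by 10 width groups was 1.96 (1.57 to 2.44). In the widest of 4 groups Pol II was present at 97.3% (95.5 to 98.5) of peaks with Pol I and 94.4% (93.8 to 94.9) of those without.

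UBF and Pol I shared a minority of their sites in NIH3T3. Of the UBF peaks, 271 (7.32%, 6.50 to 8.20) overlapped a Pol I peak, and 294 Pol I peaks (20.9%, 18.8 to 23.1) overlapped a UBF peak. Random placement gave 0.0745% and 0.207%, so that the observed shares were 98.2 times (87.2 to 110) and 101 times (90.8 to 112) as high. Of the 271 shared UBF peaks, 136 had Pol II and all 3 active marks, and 88 had none of the Pol II and histone lists. With a peak centre within 1000 bp the ratios were 66.1 and 46.5. With at least 50% of the peak covered, 3 UBF peaks (0.081%, 0.0167 to 0.237) remained in Pol I, 30 times random (6.19 to 87.6). The median Pol I peak, at 230 bp, is too narrow to cover 50% of the median UBF peak, at 981 bp. In the other direction 282 Pol I peaks (20.01%) remained in UBF, 122 times random. In the wider 50% of each list, an alternative added after the data were seen, the shares were 4.48% and 13.1%. H3K9me3 was present at 30.6% of UBF peaks with Pol I (25.2 to 36.5) and at 15.1% of those without (13.9 to 16.3).

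Over the whole lists, Pol I peaks were found in active chromatin more often than UBF peaks. Pol II and all 3 active marks were met by 54.2% (51.5 to 56.8) of Pol I peaks and 47.5% of UBF peaks. The lists differ in length and their thresholds are unknown. In the widest of 4 width groups of UBF peaks this share was 87.9%, but the Pol I list was not cut there. In the wider part of each list, an alternative added after the data were seen, Pol I peaks stayed above UBF peaks. The shares were 71.2% against 67.1% for Pol II, with overlapping intervals, and 82.0% against 68.1% for H3K4me3. They were 78.7% against 67.5% for H3K9ac and 82.4% against 68.1% for H4 hyperacetylation. The share with Pol II and all 3 active marks was not computed there. The next values are for the whole Pol I list. Pol I peaks overlapped Pol II at 58.3% (55.7 to 60.9), H3K4me3 at 68.9% (66.4 to 71.3), H3K9ac at 68.8% (66.4 to 71.3) and H4 hyperacetylation at 71.3% (68.9 to 73.7), and H3K9me3 at 16.7% (14.8 to 18.7). The ratios to random were 35.7, 24.1, 24.4, 21.2 and 10.8. Pol I peaks without UBF overlapped H3K4me3 at 72.6% (69.8 to 75.2), above the 55.1% (49.2 to 60.9) of Pol I peaks with UBF. Pol II was met by 57.5% (54.5 to 60.4) of Pol I peaks without UBF and 61.6% (55.7 to 67.2) of those with UBF, with overlapping intervals. H3K9me3 was met by 13.3% (11.3 to 15.4) without UBF and 29.6% (24.4 to 35.2) with UBF.

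The widest peak of both the UBF and the Pol I list lay at the same place, on chromosome 17 of mm9. The UBF peak ran from 39979429 to 39986294 (6865 bp), and 5 Pol I peaks lay inside it, the widest from 39979939 to 39983333 (3394 bp). Pol II, H3K4me3, H3K9ac, H4 hyperacetylation and H3K9me3 each had 1 peak over the same interval, of 6010 to 6622 bp. The files give no gene for this interval, and no mm9 annotation was used here. The GRCm38 gene table lists a ribosomal RNA pseudogene, Rn18s-rs5, on chromosome 17. Its position was not carried to mm9, so whether the interval is a copy of the ribosomal RNA genes was not tested. The peaks of every list at this place are therefore not read as joint binding at an ordinary site. The next widest UBF peak lay on chromosome 5, from 143573699 to 143580012 (6313 bp), with Pol II, the active marks and H3K9me3 and no Pol I. Of the 10 widest UBF peaks, 9 overlapped Pol II, 9 H3K4me3, 9 H3K9ac, 10 H4 hyperacetylation, 6 H3K9me3 and 3 Pol I. The exception to Pol II, H3K4me3 and H3K9ac was the third widest, on chromosome 5 from 15203401 to 15207910. Of the 10 widest Pol I peaks, all 10 overlapped Pol II and each active mark, and 4 overlapped UBF.

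UBF peaks were clustered at a few places. The fullest 100-kb window, on chromosome 13 from 23600001 to 23700000, held 13 UBF peaks, and the windows from 21800001 and from 23800001 on the same chromosome held 9 each. One window on chromosome 3, from 96000001, and one on chromosome 6, from 52100001, held 6 each. In 100 random placements the fullest window held between 3 and 5 peaks. All 31 UBF peaks in the 3 windows of chromosome 13 overlapped Pol II, H3K4me3, H3K9ac and H4 hyperacetylation, none overlapped H3K9me3, and 1 overlapped Pol I. The 6 peaks of the window on chromosome 3 overlapped Pol II and every active mark, with 1 in H3K9me3. On chromosome 6, 4 of 6 had Pol II. Pol I had its fullest windows elsewhere, with 6 peaks each on chromosome 11 from 68800001 and from 98700001.

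**Figure D3:**
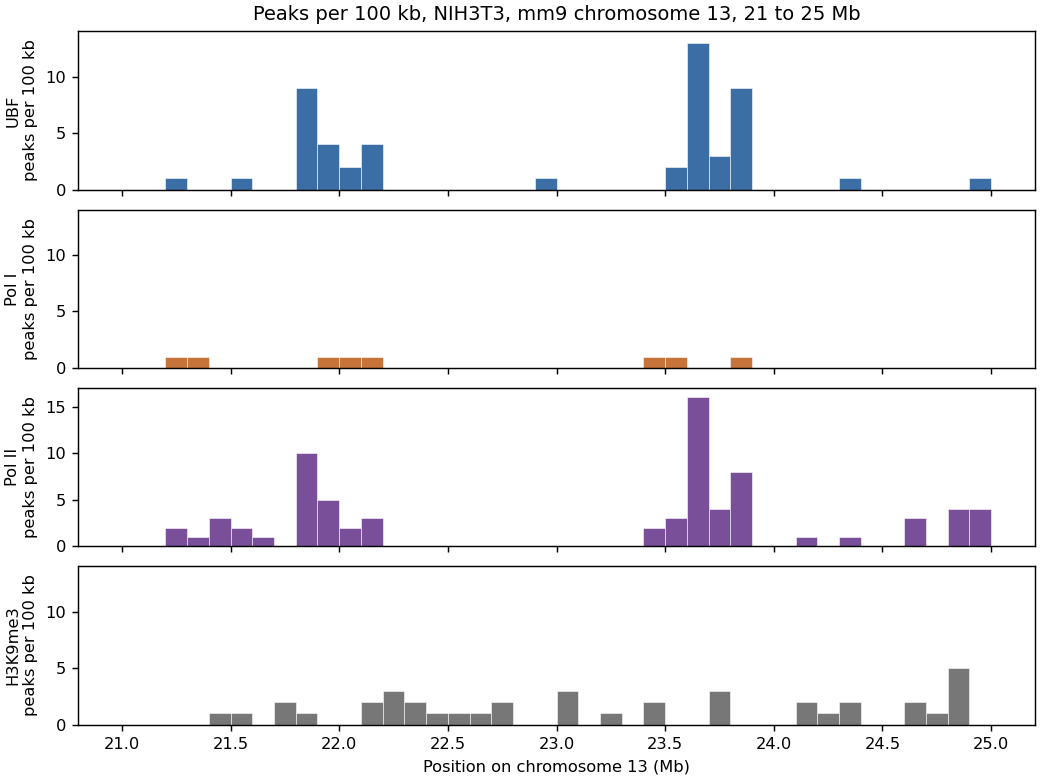
Peaks per 100 kb by peak centre on mm9 chromosome 13 in NIH3T3 cells, for UBF, Pol I, Pol II and H3K9me3; x axis, position in Mb, y axis, number of peaks. The 3 fullest UBF windows hold 13, 9 and 9 peaks and coincide with windows of 16, 10 and 8 Pol II peaks, whereas no window shown holds more than 1 Pol I peak.

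In HMEC the question was whether UBF and Pol I lie together in human epithelial cells. Few sites were shared: 258 of 9478 UBF peaks (2.72%, 2.40 to 3.07) overlapped Pol I and 266 of 9294 Pol I peaks (2.86%, 2.53 to 3.22) overlapped UBF. These shares were 9.29 times (8.21 to 10.5) and 9.64 times (8.53 to 10.8) those of random placement, and none of the 1000 placements reached them. The widest HMEC Pol I peak covered 45535 bp of the unplaced contig GL000220.1, from 101469 to 147004, on which neither UBF list held a peak. The UBF lists held few peaks on contigs or chromosome Y at all, 4 in HMEC and 12 in HMLER, against 19 in HMEC Pol I. The filters applied to each list are unknown, so the missing peak does not show that UBF was absent there. The next were on chromosome 16 from 46385805 to 46397028 (11223 bp) and on chromosome 1 from 228762332 to 228768749 (6417 bp), the latter overlapping a UBF peak of HMLER. Of the 10 widest Pol I peaks, none overlapped a UBF peak of HMEC. The fullest Pol I window, with 23 peaks, lay on chromosome 1 from 145300001, and no UBF peak of either line overlapped them. With at least 50% of the peak covered, the share of UBF peaks in Pol I was 0.96% (0.774 to 1.18, 91 peaks), and with a peak centre within 1000 bp of the other list it was 4.87% (4.45 to 5.33). For Pol I peaks in UBF these shares were 2.22% and 5.12%.

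The last question was how UBF binding differed between HMEC and the tumorigenic HMLER. The HMLER list held 3.41 times as many peaks and covered 38.2 Mb against 5.24 Mb, with a mean width of 1183 bp against 553 bp. Of the 9478 HMEC peaks, 5382 (56.8%, 55.8 to 57.8) overlapped an HMLER peak, which was 26.5 times random placement (26.0 to 26.9). In the other direction 4726 HMLER peaks (14.6%, 14.3 to 15.0) overlapped an HMEC peak, 24.0 times random (23.4 to 24.7). These shares moved with peak width and list length. In alternatives added after the data were seen, the share of HMEC peaks was 41.1% with all peaks set to 500 bp, 41.2% with the HMLER list reduced to its 9478 widest peaks and 16.7% with a random reduction to that length. The share of HMLER peaks was 34.3% with the widest peaks and 2.63% with at least 50% of the peak covered. Without a second list for either line, the difference cannot be set against the spread between cultures, and it was not tested.

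The shared UBF sites were the wider ones in HMLER. In the widest of 4 width groups of the HMLER list (1506 to 12457 bp) 37.1% of peaks (36.0 to 38.1) were also in HMEC, against 2.08% (1.78 to 2.42) in the narrowest group (191 to 683 bp). HMLER peaks shared with HMEC had a median width of 1761 bp and those absent from HMEC 900 bp. In HMEC the medians were 502 bp for shared peaks and 424 bp for peaks absent from HMLER. HMEC UBF peaks with Pol I were found in HMLER more often, at 77.5% (71.9 to 82.5), than those without, at 56.2% (55.2 to 57.2).

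The share of HMEC peaks with an HMLER peak differed between the fullest windows. The window on chromosome 22 from 46400001 held 20 HMEC peaks, 19 of them in HMLER, and the window on chromosome 7 from 27100001 held 16, 15 of them in HMLER. On chromosome 1, the windows from 145000001, 145100001 and 145200001 held 22, 13 and 16 HMEC peaks, of which 5, 2 and 3 were in HMLER. The strongest shared site by the rule of the worse rank lay on chromosome 8, from 29204942 to 29208272 in HMEC and from 29204284 to 29210922 in HMLER. On chromosome 17 an HMEC peak from 79477644 to 79479390 lay inside an HMLER peak from 79475266 to 79483373. The widest HMLER peak, on chromosome 7 from 5457780 to 5470237 (12457 bp), contained an HMEC peak from 5459510 to 5461042.

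Of the 10 widest HMLER peaks, 9 overlapped a UBF peak of HMEC, and of the 10 widest HMEC peaks, 5 overlapped one of HMLER. The widest HMLER peak absent from HMEC lay on chromosome 20 from 60939180 to 60946605 (7425 bp), followed by chromosome 19 from 1465199 to 1471896 (6697 bp) and chromosome 15 from 75742517 to 75749094 (6577 bp). The widest HMEC peak absent from HMLER lay on chromosome 7 from 16436585 to 16440484 (3899 bp), followed by chromosome 1 from 145056658 to 145060318 (3660 bp) and chromosome 12 from 29943756 to 29947329 (3573 bp). The distribution over chromosomes differed as well. Chromosome 19 held 6.16% (5.88 to 6.45) of the HMLER peaks absent from HMEC, against 3.38% (2.91 to 3.90) of the HMEC peaks shared with HMLER and 3.20% (2.68 to 3.78) of those absent from HMLER. Chromosome 4 held 2.35% (2.18 to 2.54), 4.35% (3.82 to 4.93) and 4.20% (3.61 to 4.86).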

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

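No paired analysis was possible because each antibody and cell line has 1 list. Of the settings chosen before the data were examined, the stronger 50% of each list and lists of equal length by the authors' score were not run because the lists hold no score, and a wider distance to transcription start sites was not run because no annotation of the builds was used. The ratio to random placement stayed above 1 for every pair of lists for which alternatives were run, under every alternative that gave a ratio. The random list reduction gave none. A ratio above 1 is a low bar, since even H3K9me3 peaks met H3K4me3 4.29 times as often as random placement. For UBF peaks in Pol II it ranged from 16.8 to 46.5, and for HMEC UBF peaks in HMLER from 16.0 to 42.0. The odds ratio of Pol II at H3K4me3 peaks with UBF stayed above 1, at 23.9 (18.8 to 30.5) with a centre within 1000 bp and 10.6 (8.15 to 13.9) in the wider 50% of each list. Stratified by H3K4me3 width, an alternative chosen after seeing the data, the 8 odds ratios at H3K4me3 peaks with UBF or Pol I were all lower than unstratified and their intervals stayed above 1, with 4 groups and with 10. Of 88 alternative shares, 41 stayed inside the main interval and 47 left it, and the cause was not tested except where stated. The 41 include the shares under the circular shift, which changes only the placements, so those could not leave it. With 50% of the peak covered, the shares of NIH3T3 UBF peaks were 0.081% in Pol I, whose median width is 230 bp against 981 bp, 46.0% in Pol II and 13.01% in H3K9me3, with 48.7% in none of the 6 lists. For NIH3T3 Pol I peaks in H3K9me3 it was 14.4%, for HMEC UBF in Pol I 0.96%, for HMEC Pol I in UBF 2.22%, for HMEC UBF in HMLER 54.5% and for HMLER UBF in HMEC 2.63%, where the HMLER peaks are the wider. With a centre within 1000 bp, NIH3T3 Pol I peaks met Pol II at 62.6%, H4 hyperacetylation at 74.7% and H3K9me3 at 21.6%; HMEC UBF met Pol I at 4.87%, HMEC Pol I met UBF at 5.12%, HMEC UBF met HMLER at 60.2% and HMLER UBF met HMEC at 15.8%.

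Without the widest 5% of UBF peaks, the shares were 48.3% in Pol II, 47.1% in H3K4me3, 46.9% in H3K9ac, 47.9% in H4 hyperacetylation, 14.3% in H3K9me3 and 45.8% in none. The next alternatives were chosen after seeing the data. In the wider 50% of each list, NIH3T3 UBF peaks met Pol I at 4.48%, Pol II at 67.1%, H3K4me3 at 68.1%, H3K9ac at 67.5% and H4 hyperacetylation at 68.1%, with 26.9% in none; NIH3T3 Pol I peaks met UBF at 13.1%, Pol II at 71.2%, H3K4me3 at 82.0%, H3K9ac at 78.7% and H4 hyperacetylation at 82.4%. In the same setting HMEC UBF met Pol I at 2.32%, HMEC Pol I met UBF at 2.45%, HMEC UBF met HMLER at 60.7% and HMLER UBF met HMEC at 16.4%. Without UBF peaks in H3K9me3, the shares were 6.06% in Pol I, 42.5% in Pol II, 42.0% in H3K4me3, 41.8% in H3K9ac and 42.4% in H4 hyperacetylation. With human peaks set to 500 bp, HMEC UBF met HMLER at 41.1% and HMLER UBF met HMEC at 11.7%. With the HMLER list reduced to its 9478 widest peaks the 2 shares were 41.2% and 34.3%, and with a random reduction HMEC UBF met HMLER at 16.7%, as fewer peaks were left to meet. Unknown depth and the missing peak scores limit every statement on sites that lack a peak.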

Other observations

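The tests of depth in HMLER, of random placement of the NIH3T3 UBF peaks without a list, of the H3K9me3 list as a whole and of the histone genes, and the stratification by 10 groups, were chosen only after the result was seen. Of the HMLER UBF peaks, 3.47% (3.27 to 3.67) overlapped a Pol I peak of HMEC, against 2.72% (2.40 to 3.07) of the HMEC UBF peaks, while the ratio to random placement was lower for HMLER, at 6.72 (6.33 to 7.11) against 9.29 (8.21 to 10.5). Of the 9294 HMEC Pol I peaks, 1151 (12.4%, 11.7 to 13.1) met a UBF peak of the longer and wider HMLER list, 6.83 times random, and 2.86% met one of HMEC, 9.64 times random. Among human chromosomes, the share of HMEC UBF peaks found in HMLER was lowest on chromosome 21, at 38.7% (29.6 to 48.5) of 111 peaks, and highest on chromosome 3, at 65.0% (60.8 to 69.0) of 540. On mouse chromosome X, 84.5% of 71 UBF peaks (74.0 to 92.0) met no Pol II or histone list, against 30.1% (24.3 to 36.4) of 236 on chromosome 11.

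The fullest UBF windows of mouse chromosomes 13 and 3 lie on the chromosomes that hold most histone genes. The GRCm38 gene table lists 67 protein-coding genes named as members of the replication-dependent histone clusters, 54 on chromosome 13 and 10 on chromosome 3, and 4 of the 5 windows with at least 6 UBF peaks lie on those 2 chromosomes. A candidate explanation is that UBF was bound at the histone gene clusters. Coordinates were not carried between builds, so a length was compared: the UBF peaks of the 3 windows on chromosome 13 span 2.05 Mb and the histone genes of that chromosome span 2.22 Mb in the table, a ratio of 0.922. The windows were chosen because they were the fullest, and the length was compared after they had been seen, with no measure of how often other spans come as close. The ratio therefore decides nothing, and binding at the histone genes stays open. An mm9 annotation was not used here.

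Of the NIH3T3 UBF peaks, 1707 met no Pol II or histone peak. Calls placed at random along the chromosomes are argued against as the whole of this class. Of the 1707 peaks, 88 met a Pol I peak, 90.7 times random placement (73.1 to 111). This speaks for those 88 and leaves the others open. Background that recurs at the same positions in both lists is not excluded by random placement, and the inputs were not analysed. The 92 Pol I peaks with UBF and none of the 5 lists had a median width of 101.5 bp. The 146 Pol I peaks with UBF, Pol II and all 3 active marks had 264 bp. Weak calls near the detection limit stay open and are consistent with the widths: in the widest of 4 width groups of UBF peaks 6.60% (5.09 to 8.40) met no list, against 46.1% of all. Width is a stand-in here, since the lists hold no score. No biological explanation was tested.

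H3K9me3 was more frequent at H3K4me3 and Pol II sites with UBF (31.9%, 29.7 to 34.2) than at those without (18.3%, 17.6 to 19.0). The share did not follow width over the whole range: from group 2 to group 10 of 10 H3K4me3 width groups it went from 9.09% to 53.1% with UBF and from 10.5% to 37.7% without, but the narrowest group stood at 66.0% with UBF (47 sites), above every other group, and at 21.7% without, above groups 2 to 8. The odds ratio was 2.09 before and 1.75 (1.56 to 1.96) after stratifying by 4 width groups. It was 1.44 (1.28 to 1.62) after stratifying by 10 groups of width and 10 of Pol II coverage. The difference was not even over the 4 groups, so 1 pooled ratio does not describe them. It was 71.4% against 26.2% in the narrowest and 38.2% against 24.7% in the widest, which has no tight upper bound (2548 to 41813 bp). In the middle groups the shares were 12.9% against 10.6% and 12.2% against 12.6%, with overlapping intervals. Width alone is therefore argued against only for the narrowest and the wider sites. In groups 2 to 4 of 10 the share was lower with UBF than without, at 9.09% against 10.5%, 10.0% against 10.8% and 12.3% against 13.1%. Signal strength that width does not capture stays open. So does background that recurs at the same positions in several lists, as the inputs were not analysed. In the narrowest of 10 groups of all H3K4me3 peaks (243 to 794 bp), the 30 with UBF had H3K9me3 at 76.7% and Pol II at 83.3%. Those without UBF had 12.7% and 12.1%. A list that marks active promoters as a whole is argued against, as 16.7% of all H3K9me3 peaks met H3K4me3, although this was 4.29 times random placement (5.71 times for Pol II), so a part of the list at active sites stays open.

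The HMLER UBF list was longer than that of HMEC. Deeper or more sensitive calling in HMLER alone was taken to keep nearly all HMEC peaks, with 90% as the bound, and 56.8% (55.8 to 57.8) were kept. The bound was assumed after the share was known. No second list of either line measures how many peaks deeper calling keeps, so this does not decide on depth. Random positions for all HMEC peaks missing from HMLER are argued against. These peaks met HMEC Pol I peaks 5.04 times (3.84 to 6.51) as often as random placement, though that rests on 58 of 4096. Background that recurs at the same positions in both HMEC lists is not excluded by this. Background calls, a difference in depth alone or together with such calls, and a difference between the lines themselves stay open, with 1 list per line.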
